A study of Homo sapiens with 2 samples.

How the data were processed

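The series held 2 samples of retina from normal human eye tissue, both described as isolated retinal mRNA from total RNA. Per the labels' protocols, human tissue had been kept in an RNA preservative, was homogenized at a larger scale than rodent tissue, and each human sample was prepared from 1 eye. The labels put both samples in 1 group, so they set up no contrast between conditions. A processed table recorded for the sample numbered 1 was at hand, with 1 column of values. No separate values of the sample numbered 2 were analysed here, and whether the column holds reads of sample 1 alone is not given in the sources used here. All values below come from that 1 column, with no replicate error.

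The deposited table gave a gene symbol and 1 value per gene. Per the submitters' processing notes, reads were aligned with GSNAP to the hg19 build and counted with HTSeq. Their versions, the gene models, the scaling and any strand setting are not given in the sources used here. The file header named no unit. The deposited values were read as RPKM, reads per kilobase of gene model scaled to a fixed library size, because of the values themselves. They were not whole, they summed to 309342 over 15773 symbols, and they moved in steps set by gene length. This was tested on 152 genes that have a single transcript in GENCODE release 29 and low values written with 3 or more decimals. For 40.8% of these genes the value times the transcript length was a whole multiple of 14.9 RPKM bases, to within 0.02 of a read, whereas the highest share in 100 shuffles of the lengths was 12.8%. On that reading 1 read on a gene of 1000 bases was worth 0.0149 RPKM and the scaling total was about 67300000 reads. Whether reads or read pairs were counted is not given, and the depth holds only if the values were scaled by the library's reads. A scaling to relative transcript numbers (TPM) with many genes left out would give steps too and no depth. Because the authors' gene lengths are not in the table, no read count or counting interval is given per gene. If the depth holds, 3 reads on a gene of 1000 bases correspond to 0.0446 RPKM, and this floor covers counting error only.

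The table had 15798 rows. The 1 row with no number was left out. Of the 22 repeated symbols, 1 had values that differed by more than 0.01, and the highest value was kept for each. Most rows came in 2 formats, and rows with fewer than 2 decimals belong to neither. Of the 1006 rows written with exactly 2 decimals, 993 stood at 1 RPKM or more and 13 below it, whereas 2378 of 14369 rows with 3 or more decimals (16.5%) stood below 1. A part of the table may thus have been filtered near 1 RPKM, so a gene missing from it was treated as not measured and never as 0. The steps were not tested on rows with fewer than 3 decimals, and their values were taken, untested, to be on the same scale. None of the 15 fixed symbols of the mitochondrial genome was in the table as analysed. Exact zeros also occurred in genes that every cell uses, so such genes are only said to be listed at 0.

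From the deposited RPKM, the number of genes at or above a detection minimum of 1 RPKM, the share of summed RPKM in the 10 most abundant genes, and the level and share of 28 gene lists were computed. The lists, the 11 rod and cone counterpart pairs and the rule for named genes were fixed before the data were examined. A list's level was the median of log2(RPKM + 1) over its measured members. The median RPKM printed with it was taken on RPKM itself. It can exceed that level, turned back to RPKM, where a list has an even number of members. The level was placed as a percentile among the medians of 10000 random lists of the same size drawn from all genes of the table. This percentile describes this column of values and is not a p-value, since genes are not replicates. The medians understate differences among low genes on the log2(RPKM + 1) scale. Where counts had been foreseen, RPKM was used and the read minimum of the plan became 1 RPKM. Named genes were the 20 most abundant, all genes of the counterpart pairs, and for each list the 2 highest members and the lowest 1. Genes on the Y chromosome, XIST, HLA genes and a few commonly deleted genes were kept in totals and never named. A few genes that this rule would name are not reported here. OPN1LW and OPN1MW, near-identical copies that share reads, were used only as their sum. Genes with near-identical copies or many processed pseudogenes, such as GAPDH, FTH1 and ribosomal protein genes, can lose reads in counting, and genes that overlap others cannot be told apart where strand was not used.

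Gene positions and transcript lengths were taken from GENCODE release 29 on GRCh38, a different build from that of the alignment, and matched by symbol for 91.6% of genes. They were used to test the steps, to weight values by length and to find sequence shared between genes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. The list percentile was tested on simulated lists of 15 genes among 15773. Of 200 unchanged lists, 2.5% passed the 95th percentile, against 84% of lists raised 4-fold and 99.5% of lists raised 16-fold. The step search, tested on 1153 simulated genes, recovered the step of 20 that had been put in. Alternatives changed the detection minimum, the pseudocount, the pool of random lists, the treatment of shared and very abundant genes, the set of pairs and the weighting by length.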

Results

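Retina from normal human eye tissue was profiled by RNA sequencing to describe which genes it expresses. The design held 1 group of 2 samples, and the table recorded for 1 of them, read as RPKM, gave values for 15773 gene symbols. With 1 column of values there was no replicate check, and every comparison below is between genes within it. Whether the column holds reads of that sample alone is not given.

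Genes of the rod photoreceptor were among the most abundant. Among the 10 most abundant genes were PDE6G, the inhibitory subunit of rod phosphodiesterase, at 5168 RPKM, 1.67% of all summed RPKM, and SAG, rod arrestin, at 3306 RPKM. The same 10 included CKB (brain creatine kinase) at 2679, GAPDH at 2665, GPX3 (a glutathione peroxidase) at 2473, TF (transferrin) at 2353, UNC119 at 2106, GNAT1 (rod transducin alpha) at 2004 and RCVRN (recoverin) at 1859 RPKM. The next 10 held NRL, the rod-determining transcription factor, at 1570, RPL3 at 1505, ENO2 at 1437, the outer segment protein gene ROM1 at 1337, FTH1 at 1202, AIPL1 at 1142, GUCA1A at 1140, GNB1 at 1112, ALDOC at 1049 and RBP3 at 1032 RPKM. In GRCh38 SAG lies on chromosome 2 from 233307816 to 233347055 and PDE6G on chromosome 17 from 81650459 to 81663112, both annotated as protein-coding.

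The 10 most abundant genes together held 10.02% of summed RPKM, the first 100 held 27.1% and the first 1000 held 58.1%. At or above 1 RPKM there were 12969 genes, 82.2% of those in the table, and 22 genes reached 1000 RPKM. The median gene stood at 5.26 RPKM, and 420 genes were listed at 0.

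Rod genes stood above their cone counterparts in all 11 pairs. All 15 genes of the rod phototransduction list were at or above 100 RPKM, with a median of 696 RPKM, above all 10000 random lists (percentile 100). The lowest was SLC24A1, the rod sodium-calcium-potassium exchanger, at 125 RPKM. The 14 entries of the cone list had a median of 22.2 RPKM (percentile 99.8), and all were above 1 RPKM. GNB3, the cone transducin beta subunit, led them at 422 RPKM, ahead of PDE6H, the cone phosphodiesterase inhibitory subunit, at 356 RPKM. The rod list made up 7.50% of summed RPKM and the cone list 0.449%. Without the 10 most abundant genes the rod share was 2.28% and the rod median 286 RPKM, and weighting by the longest transcript moved the cone share to 0.243%.

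The median ratio of rod to cone gene over the pairs was 19.9 and its range was 2.64 to 136. The widest gap was between the channel subunits CNGB1 at 286 RPKM and CNGB3 at 2.11 RPKM, a ratio of 136. CNGA1 at 127 RPKM and CNGA3 at 4.10 RPKM differed 30.96-fold. Transducin alpha was 64.7-fold higher for GNAT1 than for GNAT2, which stood at 30.96 RPKM. The catalytic phosphodiesterase genes PDE6A at 696 and PDE6B at 281 RPKM were 76.3-fold and 30.8-fold above their shared cone counterpart PDE6C at 9.12 RPKM. SLC24A1 was 19.9-fold above SLC24A2 at 6.25 RPKM, and the rod kinase gene GRK1 at 171 RPKM was 19.2-fold above GRK7 at 8.94 RPKM. The inhibitory subunits PDE6G and PDE6H differed 14.5-fold, and SAG was 13.6-fold above cone arrestin ARR3 at 244 RPKM. The gap was narrower for the transducin gamma genes, 6.53-fold between GNGT1 at 466 and GNGT2 at 71.4 RPKM. It was narrowest for GNB1 over GNB3, 2.64-fold. GNB1 is also used by many other cell types, which would widen this gap, whereas any expression of GNB3 outside cones would narrow it. The values do not tell which cells the reads of either gene came from. The cone opsin genes summed to 208 RPKM, of which the red and green opsin copies made up 182 RPKM. Reads that fit both copies can be lost in counting, so this sum is uncertain. The ratio of the summed pair values was lower than the median ratio, at 11.9.

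**Figure D1:**
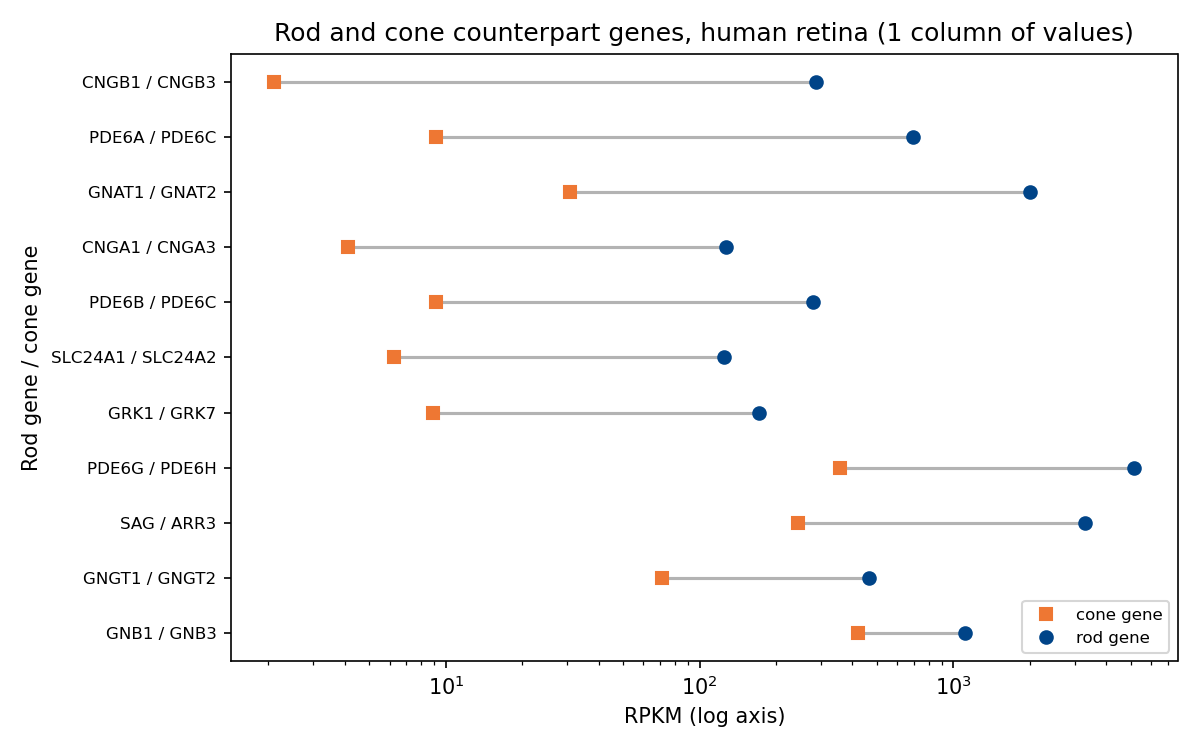
RPKM on a log axis for the 11 rod genes (circles) and their cone counterparts (squares) in the 1 column of values, with a line joining each pair and pairs ordered by ratio. Every rod gene lies to the right of its cone counterpart, by 2.64-fold for GNB1 and GNB3 up to 136-fold for CNGB1 and CNGB3.

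Genes used by both photoreceptor types were also abundant. The shared photoreceptor list of 30 genes had a median of 145 RPKM (percentile 100), led by UNC119 and RCVRN, and 18 of its genes reached 100 RPKM. EYS, a large extracellular photoreceptor protein gene, was its lowest member at 1.81 RPKM. The ribbon and photoreceptor synapse list had a median of 87.3 RPKM (percentile 100), with the vesicular glutamate transporter gene SLC17A7 at 409 and VAMP2 at 350 RPKM, and PCLO lowest at 3.38 RPKM. The photoreceptor cilium list was lower, with a median of 13.1 RPKM (percentile 99.2). ARL3 and MAK led it at 74.5 and 62.1 RPKM, and RPGRIP1L was lowest at 0.981 RPKM. When members and random genes under 1 RPKM were dropped, the cilium list fell to percentile 94.8.

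Transcription factors of the retina had a median of 23.5 RPKM over 25 genes (percentile 99.99), of which 24 were at or above 1 RPKM. NRL and RAX2, a homeobox factor of photoreceptors, were highest at 1570 and 356 RPKM. ATOH7, which specifies ganglion cells in development, was lowest at 0.45 RPKM. The visual cycle list had a median of 29.3 RPKM (percentile 99.95), but of 3.60 RPKM without its members shared with another list. Most of its members also sit in the shared photoreceptor, Müller glia or pigment epithelium lists. The lower median thus rests on the few genes left and does not describe the visual cycle as a whole. The retinoid carrier gene RBP3 and RDH12, a photoreceptor retinol dehydrogenase, were highest at 1032 and 383 RPKM. STRA6, the gene of a receptor for retinol-binding protein, was lowest at 0.239 RPKM.

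Among the lists of other retinal cells, that of Müller glia had the highest median. Its 17 marker genes had a median of 74.6 RPKM (percentile 100), led by CLU at 625 and VIM at 449.8 RPKM, with DIO2 lowest at 3.05 RPKM. A list's level also depends on how specific its chosen markers are, so these medians do not rank the cell types by abundance. Bipolar cell markers had a median of 17.5 RPKM (percentile 99.6). CABP5 and PCP2, markers of bipolar cells, reached 324 and 143 RPKM, and NYX, nyctalopin, was lowest at 0.865 RPKM. Amacrine cell markers had a median of 10.3 RPKM (percentile 90.8), led by CALB2 at 39.3 and the glycine transporter gene SLC6A9 at 37.3 RPKM. The acetylcholine transporter gene SLC18A3 was lowest at 0.749 RPKM. Horizontal cell markers had a median of 6.36 RPKM (percentile 60.8, or 36.6 against random genes at or above 1 RPKM). SEPT4, which other cell types also express, stood at 283 RPKM in that list, 19.6-fold above the next member CALB1 at 14.4 RPKM, and ONECUT3 was lowest at 2.15 RPKM. Ganglion cell markers had a median of 5.20 RPKM (percentile 48.9), with SNCG at 235 and the neurofilament gene NEFL at 84.6 RPKM, and POU4F3 lowest at 0.126 RPKM. Across these 8 retinal cell lists, photoreceptors included, 125 of 130 distinct members were at or above 1 RPKM, and they held 13.2% of summed RPKM.

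Markers of other glia, immune cells and vessels had list medians near or below that of all genes. Astrocyte markers had a median of 5.62 RPKM (percentile 48.1), with GFAP at 111, SLC1A2 at 11.7 and GJA1 lowest at 0.266 RPKM. Markers of microglia and macrophages had a median of 2.47 RPKM (percentile 8.89, or 57.4 when members and random genes under 1 RPKM were dropped), with CD74 at 70.4, C1QB at 16.2 and PTPRC at 0.206 RPKM. Endothelial cell and pericyte markers had a median of 1.90 RPKM (percentile 4.27, or 26.0 with such genes dropped), with KDR at 30.0, CLDN5 at 9.71 and ANGPT2 at 0.0903 RPKM. Of 8 oligodendrocyte markers 2 exceeded 1 RPKM, among them MBP at 2.94 RPKM. The list median was 0.0103 RPKM, below every random list (percentile 15.1 for the 2 members above 1 RPKM against random genes at or above 1 RPKM), and MAG was among the 2 members listed at 0.

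Among markers of tissue outside the retina, red blood cells included, the lists differed. Of 76 distinct measured members of these 7 lists, 53 were under 1 RPKM, with those listed at 0 counted among them. In the retinal pigment epithelium list, however, 12 of the 20 members were at or above 1 RPKM. Together the 7 lists held 0.335% of summed RPKM, or 0.174% with values weighted by transcript length. The pigment epithelium list had a median of 1.80 RPKM (percentile 1.10, or 25.7 with members and random genes under 1 RPKM dropped), and of 0.955 RPKM without members shared with another list. RGR, a retinal opsin also known in Müller glia, reached 120 RPKM, SERPINF1 reached 68.0 RPKM, and the pigment gene TYR was listed at 0. The lens list had a median of 0.0919 RPKM and a single abundant gene, CRYAA (alpha-A crystallin), at 668 RPKM. The next lens gene, CRYGS, stood at 3.95 RPKM, and CRYBA4 was among the 4 members listed at 0. CRYAA lies on chromosome 21 from 43169008 to 43172805 in GRCh38. Without CRYAA the 7 lists held 0.119% of summed RPKM. Choroid and sclera fibroblast markers had a median of 0.496 RPKM, with FMOD at 4.84, COL1A2 at 4.26 and OGN at 0.0145 RPKM. All 8 measured cornea and conjunctiva markers were under 1 RPKM, the highest being ALDH3A1 at 0.349 RPKM, and KRT4 was listed at 0. In the ciliary body and iris list WFDC1 stood at 27.2 and CPAMD8 at 1.39 RPKM, and PITX1 was among the 3 listed at 0. Skeletal muscle markers had a median of 0.245 RPKM, with TNNC2 at 4.14, MYLPF at 0.522 and MYH1 listed at 0. Of the red blood cell markers HBB, beta globin, stood at 2.35, HBA1 (near-identical to HBA2, so uncertain) at 0.387 and SLC4A1 at 0.006 RPKM. The background list of genes silent in retina had 5 of its 22 members in the table, among them INS and GCG, and all 5 were listed at 0.

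Genes of energy supply and of basic cell function were high. All 17 glycolysis genes were above 30 RPKM, with a median of 212 RPKM (percentile 100). GAPDH and the neuronal enolase gene ENO2 led them at 2665 and 1437 RPKM, and HK2 was lowest at 31.8 RPKM. Housekeeping genes had a median of 62.9 RPKM (percentile 100), with GAPDH first, ACTB at 469 RPKM and TBP lowest at 9.36 RPKM. Stress and immediate early genes had a median of 24.5 RPKM (percentile 99.97), led by the metallothionein gene MT2A at 60.7 and DUSP1 at 45.0 RPKM, with ATF3 lowest at 0.514 RPKM. No member of the list of mitochondrially encoded genes was in the table as analysed, so that list has no value.

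**Figure D2:**
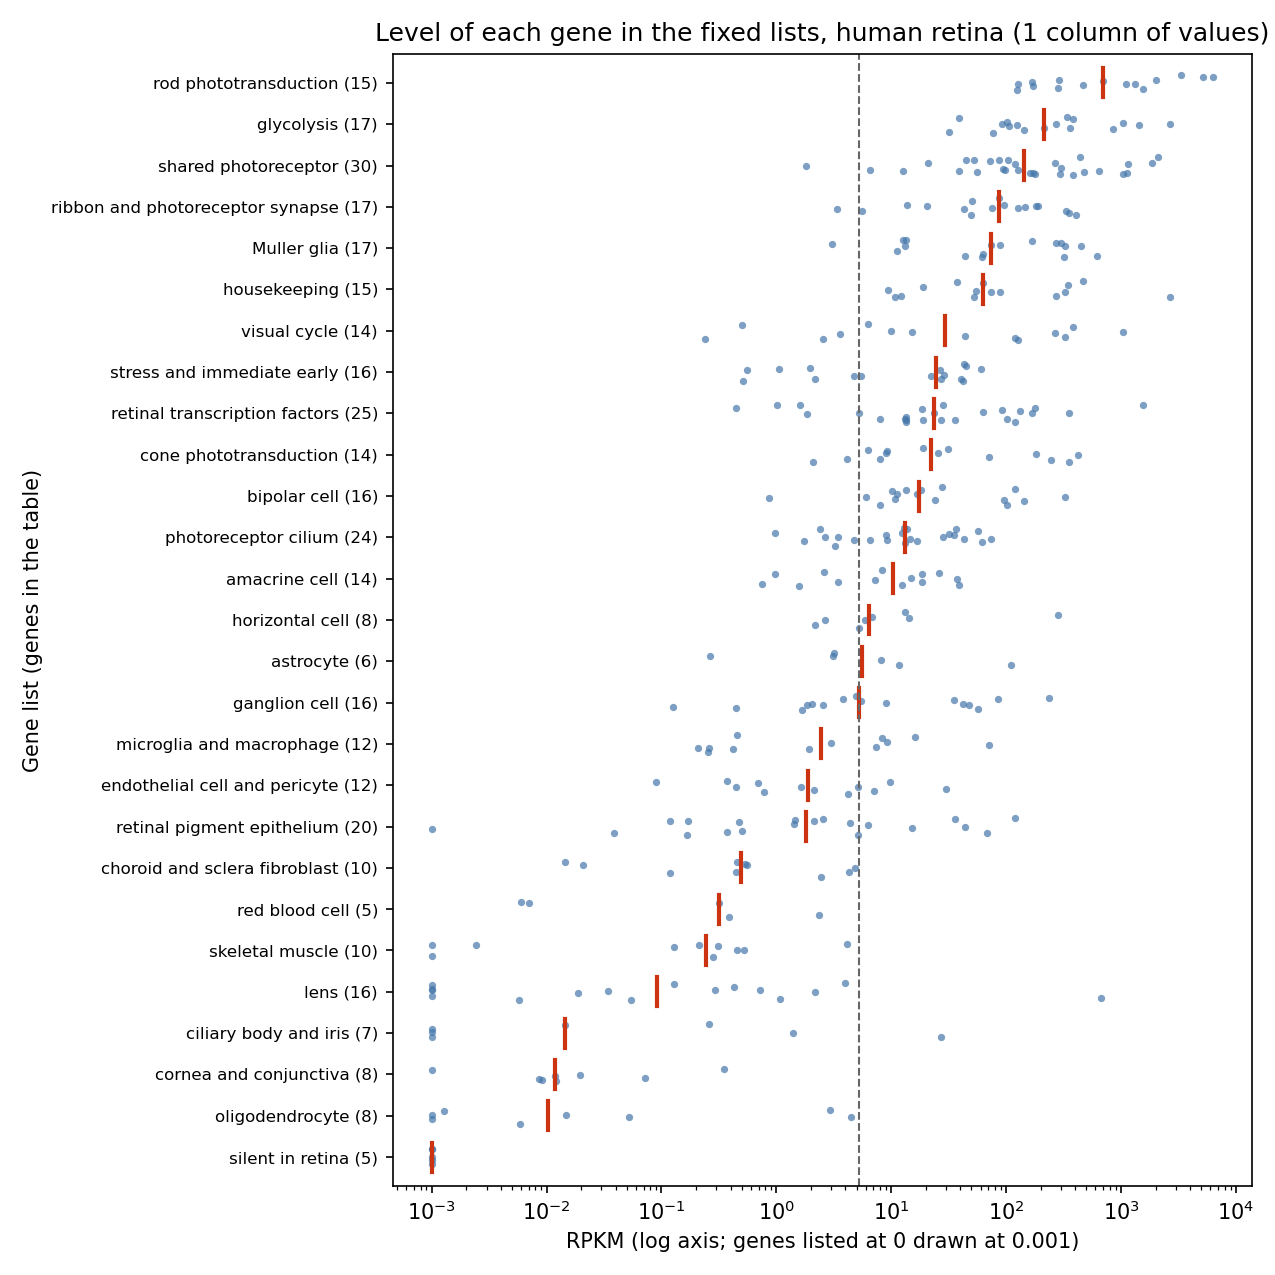
RPKM on a log axis for each measured member (points) of the fixed gene lists in the 1 column of values, with the list median as a red bar, the median of all genes (5.26 RPKM) as a dashed line, and the number of measured genes in brackets. Rod phototransduction has the highest median (696 RPKM), and the medians of the lists of neighbouring tissues lie left of the dashed line, although single genes such as CRYAA at 668 RPKM lie far to its right.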

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

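The alternatives that used RPKM minimums other than 1, weighting by the longest transcript, matching on length and leaving out CRYAA were chosen after seeing the data. No paired analysis was possible because there was 1 group and 1 column of values, and for the same reason no library could be left out and the agreement of both samples was not computed. Totals without mitochondrial genes gave no value because none was in the table, minimums of 3 counts and 1 CPM were not run because the table holds no counts, and dividing by length was not run because the values already are per kilobase. The number of detected genes was 5388 with a minimum of 10 RPKM, and stayed within 1.5 times 12969 at the other minimums (10009 to 15352). Detected members of the retinal cell lists ranged from 96 to 130. Weighting by the longest transcript moved the share of the 10 most abundant genes from 10.02% to 12.8%, that of the rod list from 7.50% to 7.04%, that of the cone list from 0.449% to 0.243%, that of tissue outside the retina from 0.335% to 0.174%, and the median rod to cone ratio from 19.9 to 29.2. Leaving out the 10 most abundant genes moved the rod list to a share of 2.28% and a median of 286 RPKM, the cone share to 0.499% and that of outside tissue to 0.373%. Without members shared between lists the cone median was 28.2 RPKM and the outside share 0.274%, and without CRYAA the latter was 0.119%. The cone list stood at percentile 99.7 against lists matched on length and 99.5 against lists of genes at or above 1 RPKM. The rod to cone ratio was 11.9 from summed values, 11.7 from sums without the most abundant gene of each side, and 25.4 without GNB1 and GNB3. All of these ratios stayed above 1. Without shared members the visual cycle median fell from 29.3 to 3.60 RPKM, over the few members left, and that of pigment epithelium from 1.80 to 0.955 RPKM. Without members under 1 RPKM they were 82.0 and 5.70 RPKM. For the other lists, 82 of 196 alternative values were equal to 3 digits and 114 moved. When members and random genes under 1 RPKM were dropped, the low lists rose, since their low members were removed by construction. Microglia and macrophages moved from percentile 8.89 to 57.4, ciliary body and iris from 0 to 42.7, skeletal muscle from 0 to 31.5, endothelial cells and pericytes from 4.27 to 26.0, pigment epithelium from 1.10 to 25.7, choroid and sclera from 0.07 to 24.6, red blood cells from 0.94 to 16.2, oligodendrocytes from 0 to 15.1 and lens from 0 to 7.26. Astrocytes moved from 48.1 to 54.1, while the horizontal cell list fell from 60.8 to 36.6 and the photoreceptor cilium list from 99.2 to 94.8. If scaled by the library's reads, depth limits low genes to about 0.0446 RPKM for 1000 bases.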

Other observations

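The tests on CRYAA, on the 4 widely used genes and on the averaging of libraries, and the gene families below, were chosen after the values were seen. The test of all genes listed at 0 was set before its result. Nuclear genes of oxidative phosphorylation stood high together. The 37 complex I subunit genes had a median of 81.3 RPKM with none under 1 RPKM, the 9 complex III genes a median of 102 RPKM, the 15 cytochrome c oxidase genes a median of 108 RPKM and the 16 ATP synthase genes a median of 105 RPKM, each above all 10000 random lists. COX8A at 398 RPKM and ATP5B at 472 RPKM led the last pair of groups. Small ribosomal subunit genes had a median of 235 RPKM and large subunit genes one of 146 RPKM, with RPL3 at 1505 RPKM.

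Potassium channel genes were low as a group, with a median of 2.19 RPKM over 77 genes (percentile 0.01), yet KCNV2, a photoreceptor channel subunit, stood at 783 RPKM. Among the 4 dopamine receptor genes DRD4 reached 126 RPKM, against 24.9 for DRD2, 7.88 for DRD1 and 2.13 RPKM for DRD5. GABA receptor genes had a median of 9.16 RPKM, led by GABRR2 at 24.0 RPKM. All 9 circadian clock genes were above 1 RPKM, from PER2 at 3.30 to CRY2 at 48.8 RPKM (percentile 96.7 for the group). Keratins (median 0.0106 RPKM, 3 of 24 genes at or above 1 RPKM) and chemokines (median 0.159 RPKM, 5 of 21) were low, with KRT10 at 13.1 and CXCL14 at 23.7 RPKM as their highest members. These medians include 10 keratins and 5 chemokines listed at 0, where lost reads cannot be told from silent genes.

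CRYAA, a gene best known from the lens, stood at 668 RPKM. Lens material in the dissected retina is a candidate source, and lens cells would bring their other abundant crystallin and membrane transcripts too. The highest of the other 15 lens list genes, CRYGS, reached 0.592% of the CRYAA value, and their median was 0.0548 RPKM, which argues against lens material as the source of most CRYAA reads. CRYAB, also a lens crystallin but placed in the Müller glia list, stood at 74.6 RPKM. Expression of CRYAA by retinal cells stays open as a hypothesis, and with 1 group no biological explanation was tested.

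Some genes that every cell uses were listed at 0. Among 249 symbols of ribosomal, translation initiation, respiratory chain and proteasome genes, 4 were listed at 0, among them RPL21, EIF3C and EIF4A1. A candidate explanation is that reads which fit more than 1 gene were not assigned. Of 380 genes listed at 0 and found in GENCODE, 28 (7.37%) had at least 90% of their sequence, as 31-base words on either strand, in another annotated gene, against 3 of 526 genes (0.57%) with values above 0 and under 0.1 RPKM, an odds ratio of 13.9 (2-sided Fisher's exact test, p = 1.55e-08). The groups were not matched on length, and a very short gene exceeds 0.1 RPKM with 1 read. Such genes could be listed at 0 but could not enter the low group. Copies that share sequence can be listed at 0 together, while the p-value treats genes as independent and so can be too small. The 4 widely used genes shared a mean of 34.7% of their sequence (SD 16.4), against 14.4% (SD 13.4) for 220 such genes at or above 1 RPKM (2-sided permutation test, p = 0.0193). EIF4A1, on chromosome 17 from 7572706 to 7579005 in GRCh38, overlaps the readthrough gene SENP3-EIF4A1 on the same strand (7563287 to 7578715), though no gene of the 4 reached the 90% mark, and the build and gene models used for counting differ from those searched here. Most genes listed at 0 had no such overlap, so these zeros may mix lost reads with genes that are silent in retina.

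The table has 1 column while the series has 2 samples, so the column might average both libraries. A mean of libraries of different depth would break the whole-read steps as reads accumulate, unless the depths stood in a simple ratio that leaves a common step. At 5 to 20 steps 41.9% of 74 genes were whole (95% Wilson interval 31.3% to 53.3%), against 39.7% of 58 genes under 5 steps and at most 16.4% with shuffled lengths, which argues against a mean that breaks the steps. Reads pooled before counting, libraries of equal depth, or depths in a simple ratio, stay open.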
